A study of Arabidopsis thaliana with 3 samples.

How the data were processed

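Transcript levels were compared between Arabidopsis thaliana seedlings (ecotype Col-0) given the auxin indole-3-acetic acid (IAA) and seedlings given the ethanol carrier alone. Per the labels, the seedlings had been grown in darkness for 4 days, were submerged in 10 µM IAA in 0.1% ethanol or in 0.1% ethanol, and were frozen after 20, 40 or 60 minutes. Total RNA of the ethanol seedlings was channel 1 and total RNA of the IAA seedlings was channel 2 of each array, per the labels. There were 3 arrays with 2 channels, 1 per time point, and no replicate of any time point.

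The deposited values were a single table of 21939 probes by 3 arrays, on a log2 scale. The base was read from the deposited values: 2 raised to each value was a multiple of 0.01 for 100% of the values on each array, within a tolerance of 1e-05, so that each log2 value stands for a ratio rounded to 2 decimals. Near a ratio of 1, 1 rounding step is 0.0144 on the log2 scale. The channel in the numerator, the dyes, the background correction, the normalization within arrays and the array model are not given in the sources used here. Spot intensities were not analysed here, so no signal over background, no level of a transcript and no depth can be stated, and the number of arrays limits the precision. The median log2 ratio was 0 at 20 minutes, 0.0144 at 40 minutes and 0 at 60 minutes, to within 3e-07. Missing values numbered 9, 10 and 7 on the 3 arrays. Columns of other samples in the table numbered 0.

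Probes were named through the platform annotation, updated by gene identifier to a RefSeq gene table of assembly TAIR10.1. Of the 21939 probes, 12195 had 1 gene, 1 had several and was left unnamed, and 9743 were not listed there and are unnamed here, which does not mean that they lack a gene. Of the 12195, 12142 matched the RefSeq table and 53 kept the annotation's name. No genome build was named by the table of values, so that no coordinates are given. Probes of 1 gene were averaged: 55 genes had several probes, with a median range of 0.135 on the log2 scale, and 3 genes had probes more than 1 log2 unit apart. Genes or unnamed probes with a value on all 3 arrays numbered 21859, of which 12127 were named genes and 9732 were unnamed probes.

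No test was made at a single time point, since each has 1 array. Genes at or beyond 2-fold were counted on each side. The mean log2 ratio over the 3 arrays was tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept, empirical Bayes moderation, two-sided, Benjamini-Hochberg over 21859 genes and probes, threshold 0.05), and the slope over time in minutes in the same way. The spread in these tests is the spread between the 3 time points, which holds changes over time as well as error, and the 3 arrays are not replicates of one another. Nothing in the labels says whether the seedlings of different times came from separate cultures. Tested on simulated data of 21859 genes with 200 changed, the test of the mean recovered 2% of genes changed by 0.585 on the log2 scale, 66% of those changed by 1, 62% of those changed by -1 and 94% of those changed by 2, with 2 false calls among 114. These simulated changes were the same at all 3 times, with the same noise on all 3 arrays. The real arrays differ in spread and real ratios can change over time, so these shares need not hold for them. The test of the slope recovered 0% at a change of 2 from 20 to 60 minutes, so a count of 0 from it carries no information.

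Before the data were examined, 30 gene lists with 451 locus codes were fixed, and 52 of these genes were measured under a name. The codes were written from memory: all 451 are in the RefSeq table, and the list's symbol matched a symbol or synonym there for 443, differing for 8. Lists with at least 3 measured members, 7 in all, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation as an alternative. The estimate rests on 2 residual degrees of freedom for the mean and 1 for the slope. A list can hardly pass that alternative, and a miss there carries little information. Fry was run beside camera and answers another question, since it tests a list against no change and camera tests it against the other genes. List medians were set against 10000 random lists of the same size, which could not be matched on expression level. A further 13 lists had 1 or 2 measured members and are given as values, and 10 lists had 0: auxin response factors, TIR1/AFB receptors, other auxin-responsive genes, ethylene biosynthesis, brassinosteroid biosynthesis and response, jasmonate response, cell cycle, seed storage markers, vascular markers, and shoot apex and epidermis markers. A list of ribosomal proteins was left out because the tables used here carry no gene descriptions.

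The genes named in the text follow a rule fixed before the data were examined. It takes the 12 highest and 12 lowest mean ratios among named genes on the same side and at least 1.5-fold at each time, the 5 highest and 5 lowest ratios per time point, the 5 largest rises and falls from 20 to 60 minutes with the 40-minute value between, and up to 4 members per list. The rule took 75 genes, of which the text names those that carry a comparison. Genes outside the rule are marked as chosen after their values were seen or, at the ends of the ratios per time point, as tied with the last gene taken. The alternatives were centring, scaling the arrays to the same median absolute deviation, other fold thresholds, the largest probe per gene, all genes with a value on an array, probes on their own, robust moderation, array weights, leaving out each array, and another adjusted p. Fits and counts on named genes alone, the counts at 2-fold of probes on their own and the count of genes at least 1.5-fold at all 3 times were added after seeing the data. So were the chromosome of the locus codes, gene families formed from symbols and the groups by time of response. Regular spacing of probes was looked for as peaks of the autocorrelation over probe numbers, averaged over the arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.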

Results

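The series followed the transcripts of dark-grown, 4-day-old Arabidopsis seedlings during the first 60 minutes in 10 µM indole-3-acetic acid (IAA), the main natural auxin. Each of 3 two-colour arrays set IAA-treated seedlings against seedlings in 0.1% ethanol harvested at the same time, at 20, 40 and 60 minutes, with 1 array per time and no replicates, so single values below carry no error. The deposited log2 ratios spanned ratios of 0.26 to 5.47 at 20 minutes, 0.31 to 10.73 at 40 minutes and 0.43 to 20.07 at 60 minutes. Their robust SD over all probes was 0.165, 0.221 and 0.110. The labels do not state which channel is the numerator, and values are printed as deposited, as a positive or a negative side. The positive side is likely IAA over ethanol. The basis is the order of the channels in the labels and the 19 measured genes of the fixed auxin-related lists: 12 were positive and 1, IAA18, was negative at all 3 times, against 12.95% and 8.82% of all named genes, and the other 6 were mixed.

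The mean ratio over the 3 times asks which transcripts differed between IAA and ethanol throughout the hour. The dyes are not given in the sources used here, and a probe-specific dye effect shared by the 3 arrays could not be told apart from such a difference. GH3.1, an enzyme of a family that conjugates auxin to amino acids, had the highest mean log2 ratio of any named gene at least 1.5-fold at each time, 2.95 ± 0.55 (SD over 3 time points). The transcription factor gene HAT2, of the HD-Zip II family, stood at 2.39 ± 0.14. AT5G66580 stood at 1.83 ± 0.14, and WAG2, a protein kinase gene related to PINOID and linked to auxin transport, at 1.40 ± 0.19. These 4 named genes passed the test of the mean ratio on the positive side (limma, Benjamini-Hochberg adjusted p = 0.0443 for GH3.1, 0.0270 for HAT2, 0.0386 for AT5G66580 and 0.0442 for WAG2), and 0 genes passed on the negative side. With 15 unnamed probes the positive calls numbered 19. At an unadjusted p under 0.05 there were 769 positive and 231 negative genes and probes, where 1093 are expected by chance. Leaving out any 1 array, or scaling the arrays to the same median absolute deviation, left 0 calls. A fit of 2 arrays has 1 residual degree of freedom, so the calls lost there say little about the ratios themselves: with 1 array left out the mean log2 ratio lay between 2.65 and 3.19 for GH3.1, 2.31 and 2.44 for HAT2, 1.75 and 1.89 for AT5G66580, and 1.33 and 1.51 for WAG2, and scaled it was 2.53 for HAT2 and 1.46 for WAG2. Fitting the named genes alone left 2 named calls, HAT2 (adjusted p = 0.0200) and AT5G66580 (adjusted p = 0.0361, limma). With array weights, which rest mainly on the 60-minute array, the calls numbered 2057 positive and 794 negative. Of the 15 unnamed calls, 10 belong to 13 probes spaced exactly 89 or 103 probe numbers apart, the leading peaks of the autocorrelation over probe numbers.

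Named genes at least 1.5-fold at all 3 times numbered 13 on the positive side and 0 on the negative side. Beside the 4 genes above they were GH3.3, LBD29, LBD16, WES1 (GH3.5), AT1G68360, AT3G51410, AT4G09890, AT1G03820 and AT4G38820, the last named after its values were seen, since it lies outside the 12 of the rule. GH3.3 had a mean log2 ratio of 2.83 ± 1.06, LBD29 2.21 ± 0.67 and LBD16 2.04 ± 0.48 (SD over 3 time points). LBD16 and LBD29 are transcription factor genes known from lateral root formation. None of these 9 passed the test over all genes (limma, adjusted p = 0.371 for GH3.3, 0.216 for LBD29 and 0.106 for LBD16). The spread in that test holds changes over time, so a ratio that rises within the hour passes less easily. GH3.3, LBD29 and LBD16 rose at each step, to 4.02, 2.91 and 2.56 at 60 minutes. GH3.1 also rose and passed. With 1 array per time a rise cannot be told apart from error. The misses of GH3.3, LBD29 and LBD16 therefore do not rank them below AT5G66580, which passed at a lower mean of 1.83. AT1G68360 stood at 1.35 ± 0.26 (adjusted p = 0.0926, limma), AT3G51410 at 1.06 ± 0.29 and AT4G09890 at 0.97 ± 0.22. Another 37 unnamed probes met the same condition.

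**Figure D1:**
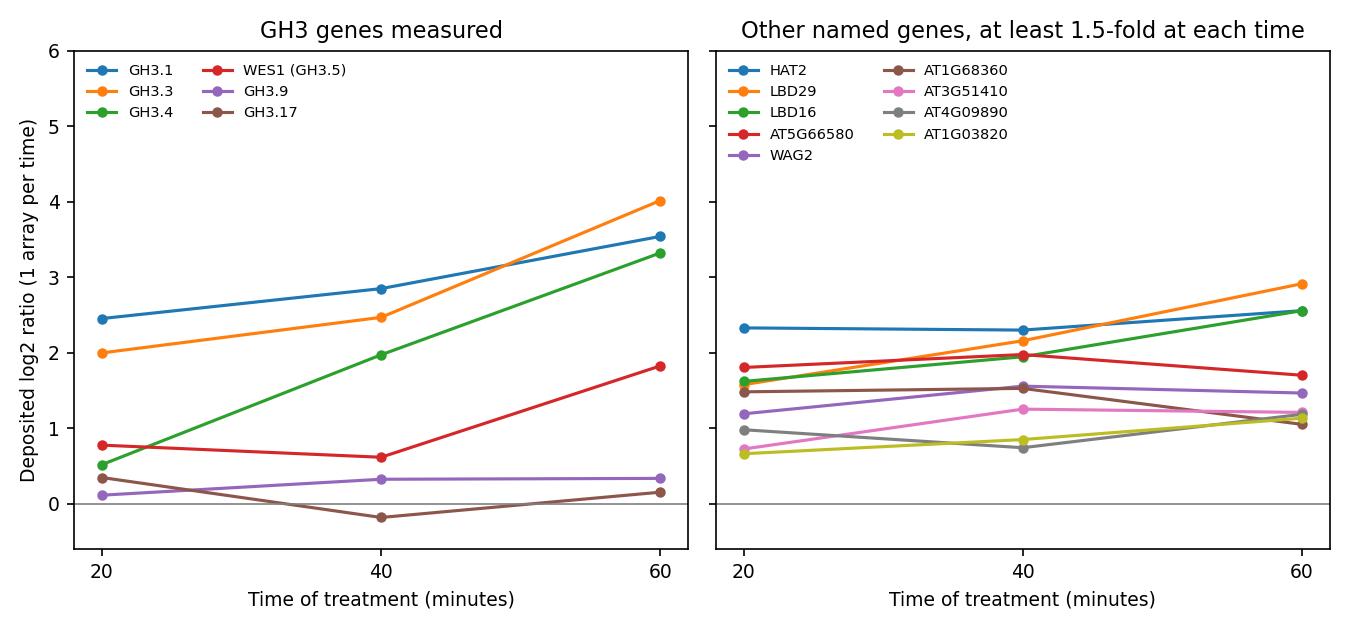
Deposited log2 ratios (vertical axes) against minutes of treatment (horizontal axes), 1 array per time; each line is 1 gene. Left, the 6 GH3 genes measured, with GH3.3 reaching 4.02 and GH3.17 between -0.18 and 0.34; right, 9 other named genes at least 1.5-fold at each time, with HAT2 between 2.30 and 2.56.

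At 20 minutes the comparison asks for the earliest differences. The highest log2 ratios among named genes were those of GH3.1 (2.45), HAT2 (2.33), GH3.3 (2.0), AT5G66580 (1.80) and AT4G27190 (1.65). The first 4 were also positive at 40 and 60 minutes, whereas AT4G27190 stood at -0.25 and 0. The lowest were AT1G17230 (-1.94), the pectate lyase gene AT59 (-1.84), AT1G68270 (-1.69), and AT1G14470, AT1G66320 and AT1G63350, tied at -1.64. At or beyond 2-fold, 20 named genes lay on the positive and 34 on the negative side, and with the unnamed probes 59 and 59. Of the 34 on the negative side, 0 were at least 1.5-fold on that side at 40 or at 60 minutes, and 14 were at least 1.5-fold on the positive side at 40 minutes. A chromosome 1 locus code was carried by 23 of the 34, where 8.78 are expected from its 25.8% share of named genes, a count made after seeing the data.

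At 40 minutes the positive side was the larger. AT5G58160 had the highest log2 ratio among named genes, 2.90, beside -0.56 at 20 and -0.32 at 60 minutes. GH3.1 followed at 2.85, AT1G21510 at 2.58 (0.31 and 0 at the other times), GH3.3 at 2.47 and HAT2 at 2.30. The lowest were AT1G62480 (-1.64), AT4G27290 (-1.47), AT5G04120 (-1.40), AT5G35480 (-1.29), and AT2G25150 and AT5G44580, tied at -1.18. Named genes at or beyond 2-fold numbered 146 on the positive and 14 on the negative side, and 266 and 31 with the unnamed probes. Of the 146, 13 were at least 1.5-fold on the positive side at 20 minutes and 16 at 60 minutes, while 15 were at least 1.5-fold on the negative side at 20 minutes. This array had the widest spread, and scaling the arrays to the same median absolute deviation changed 266 to 66 and 31 to 8.

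At 60 minutes auxin-related genes led among the named genes. The highest named genes were GH3.3 (log2 ratio 4.02, a ratio of 16.2), GH3.1 (3.54), GH3.4 (3.32), LBD29 (2.91), and LBD16 and HAT2, tied at 2.56. The lowest were AT3G20150 (-1.22), AT2G32580 (-1.09), AT3G10040 (-1.03), AT5G35510 (-0.89) and AT5G46300 (-0.86). AT3G10040 is HRA1, a transcription factor gene of the low-oxygen response, and it was also negative at 20 minutes (-0.38) and 40 minutes (-0.43). Named genes at or beyond 2-fold numbered 42 on the positive and 3 on the negative side, and 98 and 3 with the unnamed probes. Scaling changed 98 to 295 and 3 to 29, so that the order of the 3 times by count on the positive side rests on leaving the arrays unscaled.

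**Figure D2:**
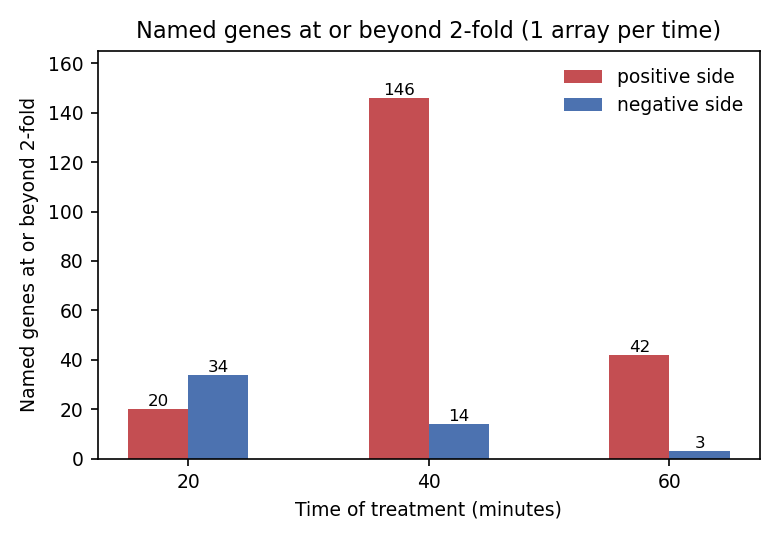
Number of named genes at or beyond 2-fold (vertical axis) at each time of treatment in minutes (horizontal axis), 1 array per time; red bars are the positive and blue bars the negative side of the deposited ratio. The positive side holds 20, 146 and 42 genes, and the negative side 34, 14 and 3.

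The trend over time asks which ratios grew or shrank within the hour. Among named genes with the 40-minute value between the others, the largest rises from 20 to 60 minutes were those of AT1G66360 (2.96 on the log2 scale), GH3.4 (2.80), AT5G01170 (2.06), AT1G19320 (2.05) and AT1G68270 (2.05). GH3.4 went from 0.52 through 1.97 to 3.32, positive throughout, whereas AT1G66360 went from -1.60 through 0.78 to 1.36. Scaling the arrays to the same median absolute deviation put GH3.4 first, at 4.30, with AT1G66360 below it. The largest falls were those of AT5G58340 (-1.73), AT5G54560 (-1.72), IAA31 (-1.55), AT2G32870 (-1.49) and AT5G35510 (-1.46). IAA31, an Aux/IAA gene, went from 1.19 through 0.04 to -0.36. In limma's test of the slope 0 genes passed on either side, with 314 positive and 127 negative at an unadjusted p under 0.05 where 1093 are expected by chance. The simulated test also made 0 calls.

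Among the 7 fixed lists with at least 3 measured members, the GH3 amido synthetases had the highest median. The list's median log2 ratio was 0.65 at 20, 1.29 at 40 and 2.57 at 60 minutes, above all 10000 random lists of 6 genes at each time. Of 6 measured members, 1 (GH3.1) passed the test over all genes, and 5 passed adjusted over the list alone (GH3.1, GH3.3, GH3.4, WES1 and GH3.9). GH3.4 had a mean of 1.94 ± 1.40 and WES1 1.07 ± 0.66, while GH3.9 stood at 0.26 ± 0.13 and GH3.17 at 0.10 ± 0.27 (SD over 3 time points), the last pair chosen after their values were seen. Camera placed the list on the positive side with an adjusted p of 1.01e-08, but the adjusted p = 0.405 with an estimated correlation. Fry, which asks whether the list differs from no change and not from the other genes, gave an adjusted p of 0.0865. The list's slope had an adjusted p of 5.22e-07 in camera and an adjusted p = 0.752 with an estimated correlation. The estimated correlation rests on 2 residual degrees of freedom for the mean and 1 for the slope, so these misses carry little information. The small p-values of camera have a limit as well. At the preset correlation they set the 6 genes against the other genes. With 1 array per time they do not measure how the ratios would vary between repeated arrays.

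The other auxin-related lists had few measured members. Of the 29 Aux/IAA repressors of auxin-responsive transcription, 5 were measured, 0 passed over all genes and 1, IAA30 (mean 0.71 ± 0.31, SD over 3 time points), passed adjusted over the list alone. IAA31 and IAA34 stood at 0.29 and 0.27 and IAA18 at -0.08. The list missed the threshold in camera (adjusted p = 0.0972, and adjusted p = 0.405 with an estimated correlation) and passed in fry, which tests against no change (adjusted p = 0.0397). The lists of LBD factors (LBD29 and LBD16), HD-Zip II factors (HAT2) and auxin transport (WAG2) had 2, 1 and 1 measured members, and all 4 passed adjusted over the list alone. For HAT2 and WAG2, alone in their lists, that p is the unadjusted one, and LBD29 and LBD16 did not pass over all genes. No adjustment was made over the lists. Of 2 SAUR genes, AT2G18010 (SAUR10) stood at a mean of 0.68 ± 0.26 and passed adjusted over the list alone, and AT4G34800 stood at -0.02. The auxin biosynthesis genes YUC4 and YUC6 stood at 0.03 and -0.04, and the sign of YUC4 turns when the arrays are scaled.

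None of the remaining 5 lists with at least 3 members passed in camera. The heat shock list had 3 members with means of -0.14, -0.12 and -0.07 and an adjusted p of 0.0556, with an adjusted p = 0.405 with an estimated correlation. The 6 cell wall loosening genes, expansins and xyloglucan endotransglucosylases, had a median mean ratio of 0.02 (adjusted p = 0.877), with XTH33 highest at 0.29. Their medians at 20, 40 and 60 minutes were 0.16, -0.09 and -0.04, the first at percentile 97.78 of random lists, and their median change from 20 to 60 minutes, -0.24, lay at percentile 1.04 (camera's slope, adjusted p = 0.222). The low oxygen list had a median of 0.00 over 3 genes (adjusted p = 0.333). AT3G10040 (HRA1) was its member with the largest mean, -0.61 ± 0.36, and passed adjusted over the list alone. The list of abscisic acid and cold response (4 genes, median 0.01, adjusted p = 0.629) was led by COR47 at -0.34; that of glutathione S-transferases (3 genes, median -0.02, adjusted p = 0.465) by GSTU20 at -0.10. In the low oxygen list and the abscisic acid and cold list the median was above 0, while the mean of the members (-0.18 and -0.06) and camera's direction were negative.

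Lists with 1 or 2 measured members are given as values of the mean log2 ratio. The root hair expansins EXPA18 and EXPA7 stood at -0.35 and -0.22, negative at all 3 times, and EXPA18 passed adjusted over the list alone. The cytokinin response regulators ARR15 and RR16 stood at 0.09 and -0.06, with RR16 at -0.89, 0.65 and 0.07 over the 3 times. The gibberellin receptors GID1A and GID1B stood at -0.08 and -0.08, the ethylene-related genes RTE1 and ARL at 0.04 and -0.01, with the sign of ARL turning under scaling, and the clock gene GI at -0.12. The light-related genes PORB and LHCB4.1 stood at 0.10 and 0.07, and the stress genes STZ and WRKY53 at 0.05 and 0.00. The single reference gene measured, AT2G28390, stood at -0.64 at 20, -0.12 at 40 and 0.15 at 60 minutes.

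The agreement between times was set out across genes, which are not independent replicates. Pearson's r over 21859 genes and probes was -0.0944 between 20 and 40 minutes, 0.0894 between 20 and 60 minutes and 0.299 between 40 and 60 minutes. Spearman's rho was -0.184, -0.0207 and 0.235, so that the sign for 20 and 60 minutes depends on the statistic. Genes and probes at or beyond 2-fold on the positive side at both times numbered 32 for 20 and 40 minutes, 30 for 20 and 60 minutes and 43 for 40 and 60 minutes, where independent lists share 0.718, 0.265 and 1.19. Most of those shared were unnamed probes. Of the 20 named genes 2-fold positive at 20 minutes, 12 were at least 1.5-fold positive at 40 and 8 at 60 minutes. Of the 146 named genes at 40 minutes, 16 were at least 1.5-fold positive at 60 minutes. Another 15 genes and probes were at or beyond 2-fold on the negative side at 20 and on the positive side at 40 minutes, where 0.718 are expected, among them AT59 and AT1G14470.

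**Figure D3:**
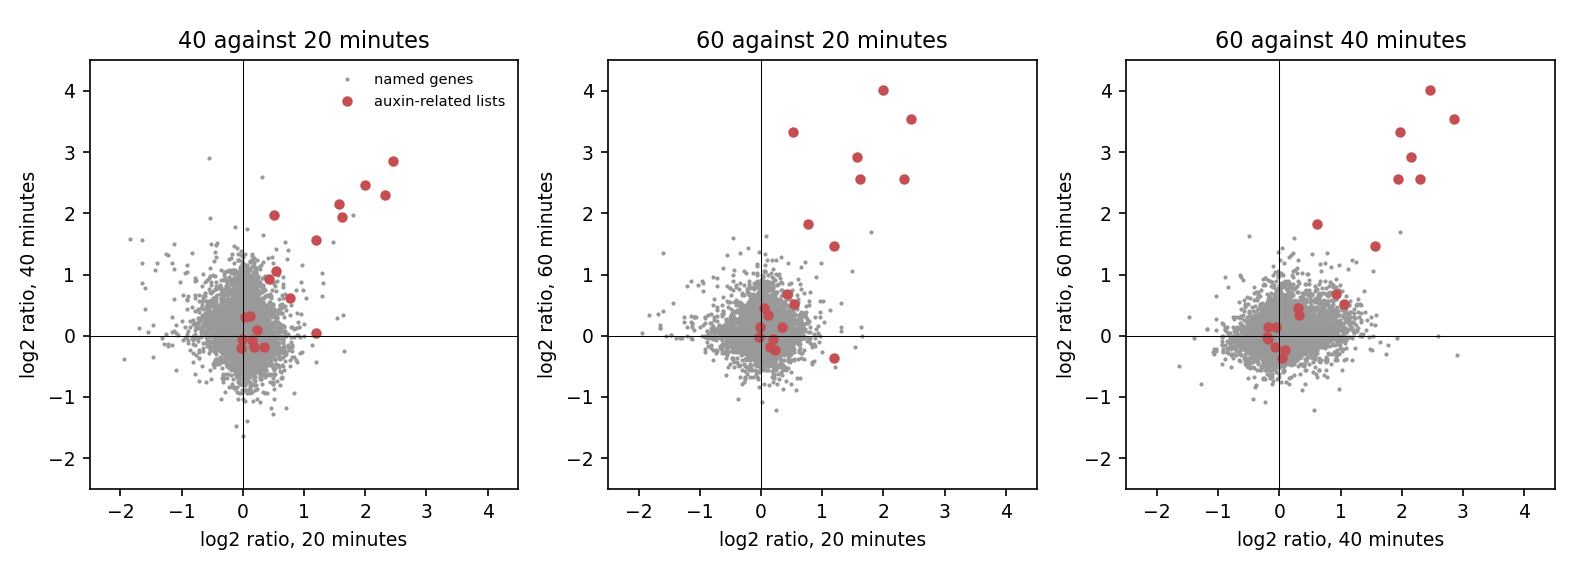
Deposited log2 ratios of named genes (grey) and of the 19 measured genes of the auxin-related lists (red), each panel setting 1 time (vertical axis) against another (horizontal axis), 1 array per time. Several red points, GH3.1 and GH3.3 among them, lie on the positive side in every panel, and grey points negative at 20 and positive at 40 minutes include AT59 (-1.84 and 1.58).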

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

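Of the tests below, all except the one on the position of probes were chosen after the result was seen. Of the 75 genes taken by the naming rule, the 8 that follow stood at least 1.5-fold on opposite sides at a pair of times. Such genes outside the 75 are not listed here. There was 1 array per time, so the difference was not tested. The log2 ratio at 40 minutes exceeded that at 20 minutes by 3.42 in AT59, by 3.21 in AT1G14470, by 2.51 in AT1G66320 and by 1.54 in RR16. The ratio at 60 minutes exceeded that at 20 minutes by 2.96 in AT1G66360 and by 2.05 in AT1G19320. In AT2G25150 the ratio at 20 minutes exceeded that at 40 minutes by 1.89, and in AT5G46300 the ratio at 40 minutes exceeded that at 60 minutes by 1.84.

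Genes and probes at least 1.5-fold negative at 20 and positive at 40 minutes numbered 62, where 14.8 are expected of independent arrays. After subtracting the median of 10 neighbours in probe number on each side, Spearman's rho of 20 and 40 minutes over all probes was -0.178, beside -0.184 before. This argues against an effect shared by neighbouring probe numbers as the whole cause of that correlation. Adjacent probe numbers correlated weakly, at rho 0.0687 at 20 and 0.0999 at 40 minutes. Places of spots on the array were not used and the 62 were not recounted, so position on the array stays open. A probe-specific dye effect that runs the other way on the 20-minute array stays open: rho of 20 and 60 minutes over genes under 1.5-fold on all arrays was -0.0382 (bootstrap SD 0.00725), but -0.00839 (bootstrap SD 0.00765) over such probes after subtracting neighbours, and the dye orientation is not given in the sources used here. A response that turns between 20 and 40 minutes and lasts stays open too: the 62 had a median log2 ratio of 0.131 at 60 minutes, which is not particular to them. The median was 0.151 in genes at least 1.5-fold positive at 40 and under 1.5-fold at 20 minutes, and 0.137 in those positive at 20 and negative at 40 minutes.

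Unnamed probes at least 1.5-fold on the positive side at all 3 times numbered 37, outside the named genes the comparisons rest on. Chance overlap is argued against, since the highest number in 1000 shuffles within arrays was 3. Repeated control spots stay open for part of them: 8 pairs lay exactly 89 or 103 probe numbers apart, against at most 3 in 10000 draws of as many unnamed probes. Both distances were chosen from the same values and the draws did not repeat that choice, which may favour the observed count. Over all probes, values 89 numbers apart correlated at rho 0.0506, 0.0907 and 0.126 at 20, 40 and 60 minutes. At 103 apart rho was 0.0535, 0.0674 and 0.0822, and at 50 apart -0.0256, -0.0254 and 0.00715. The spacing is thus not particular to these probes, and the draws did not carry it. The 8 pairs therefore cannot decide whether these are control spots. The 13 probes in these pairs had medians of 1.15, 1.37 and 1.19 over the 3 times. Without these 13, 24 probes were left, where 10.4 are expected at the rate of named genes. Genes responding to IAA may be among them, but that rate does not account for all 24. What the 24 probes measure stays open.

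The GH3 genes had a median change of 1.07 on the log2 scale from 20 to 60 minutes, positive in 5 of 6 members. Larger ratios over all probes of the 60-minute array are argued against as the whole cause: the robust SD at 60 minutes was 0.667 of that at 20 minutes (bootstrap SD 0.00685) and the SD 0.918 of it (bootstrap SD 0.0158). Scaling the arrays to the same median absolute deviation gave the GH3 genes a larger median change, 2.32. That increase follows from the narrower robust SD at 60 minutes and is not separate evidence. Larger ratios of responding genes alone on that array stay open: the 20 other named genes at least 1.5-fold at 40 minutes and in the mean of 20 and 60 minutes changed by a median of 0.216 (bootstrap SD 0.235), under the bound of 0.534 set from the GH3 change by less than 2 bootstrap SD. A response that grows with time stays open too, since the design has 1 array per time. Camera with an estimated correlation gave the list's slope an adjusted p of 0.752. With 1 residual degree of freedom a list can hardly pass that test, so it cannot decide the question.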

How the results depend on the processing

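The fits and counts on named genes alone, the counts at 1.5-fold at all 3 times, and the counts at 2-fold of probes on their own were added after seeing the data; the other alternatives were planned. Causes were not tested except where the construction gives them. Centring each array, the largest probe per gene, all genes with a value on an array and probes on their own left the counts at 2-fold within 1.5 times. Counts at 2-fold on the positive side at 20, 40 and 60 minutes became 307, 1181 and 473 at 1.5-fold and 13, 37 and 23 at 3-fold, and on the negative side 274, 303 and 74, and 13, 2 and 0, as looser and stricter thresholds must. Named genes alone, a smaller set, gave 20, 146 and 42 on the positive and 34 and 14 on the negative side at 20 and 40 minutes. Scaling the arrays to the same median absolute deviation gave 66 and 295 positive and 8 and 29 negative at 40 and 60 minutes. This follows from the construction, which shrinks every ratio of the 40-minute array, the widest, and enlarges every ratio of the 60-minute array, the narrowest. Turning every ratio exchanges the sides, to 31 and 3 positive and 266 and 98 negative at 40 and 60 minutes.

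The 19 positive calls of the mean ratio became 0 under scaling, 0 with any 1 array left out (1 residual degree of freedom, which says nothing of stability) and 2 with named genes alone fitted, where the 4 named calls also became 2. They became 2057 positive and 794 negative with array weights, which gave the 60-minute array 6.70 against 0.397 and 0.377, so that the count rests mainly on 1 array. Centring gave 20 positive calls with all 19 shared, robust moderation 18 with 18 shared, and an adjusted p of 0.1 gave 22. The test of the slope made 0 calls in each alternative run. The 50 genes and probes at 1.5-fold on the positive side at all 3 times became 13 with named genes alone and 66 to 141 with 1 array left out, and the 0 on the negative side became 1 to 4.

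The GH3 list passed in camera and not in fry (adjusted p = 0.0865) or with an estimated correlation (adjusted p = 0.405), and the Aux/IAA list passed in fry (adjusted p = 0.0397) and not in camera. Fry tests a list against no change and camera against the other genes, so these answer different questions. The estimated correlation rests on 2 residual degrees of freedom, so a miss with it carries little information. The pass of the GH3 list in camera depends on the preset correlation of 0.01, where the estimate was 0.482. With 1 array left out the Aux/IAA median ranged from 0.0458 to 0.248, lowest without the 20-minute array, and the GH3 median from 0.969 to 1.93. The correlations of 20 with 40, 20 with 60 and 40 with 60 minutes were -0.184, -0.0207 and 0.235 by Spearman, -0.114, 0.0590 and 0.279 without the auxin-related lists, and -0.193, -0.00938 and 0.186 without genes at or beyond 1.5-fold, so that the 20 with 60 value changes sign; the cause was not tested.

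Among the named genes' single values, under scaling 64 kept their sign and their side of the threshold (with no test, they moved by less than the robust SD of the array), 20 moved, 4 lost the call and 4 changed sign, all 4 near 0: YUC4 (-0.0169), ARL (0.00264), GSTU25 (0.0152) and AT4G17260 (-0.0188). Centring changed the sign of AT4G17260 (-0.00415) and left 91 others. Turning the ratios changes only the sign of a named gene's value and was not tabulated. An intensity trend and a filter on weak signal were not run, because the values used here hold no level, and no other log base was run, because the values settle it; signal over background is unknown for the same reason. Each ratio already pairs IAA with ethanol on 1 array. No paired analysis was possible beyond that because the labels give no replicate numbers.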

Other observations

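All results in this part were looked for after seeing the data. GH3.4, AT1G03990 and AT1G14500 were at or beyond 2-fold on the positive side at 40 and 60 minutes and under 1.5-fold at 20 minutes, 3 genes where 0.499 are expected of independent arrays. AT1G03990 stood at 0.18, 1.18 and 1.24, and AT1G14500 at 0.20, 1.12 and 1.09. Another 8 named genes were at or beyond 2-fold on the positive side at 20 minutes and under 1.5-fold at 40 and 60 minutes, fewer than the 18.4 expected of independent arrays. IAA31 was among them, as were AT4G27190, AT2G32870, AT5G58340 and AT5G54560. AT5G35480 was the 1 named gene at least 1.5-fold on the negative side at both 40 and 60 minutes (-1.29 and -0.79), where 0.548 are expected.

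The locus codes of the genes on the negative side at 20 minutes were unevenly spread over the chromosomes. At or beyond 1.5-fold, 78 of 155 carried a chromosome 1 code, where 40.01 are expected, and at 2-fold 23 of 34. On the positive side at 20 minutes the counts at 1.5-fold were 48 of 150, where 38.72 are expected. At 40 minutes, 137 of 694 on the positive side and 66 of 166 on the negative side carried one, where 179.14 and 42.85 are expected. At 2-fold the 40-minute counts were 36 of 146 (37.69 expected) and 4 of 14 (3.61 expected). At 60 minutes they were 91 of 272 on the positive side (70.21 expected) and 4 of 40 on the negative side (10.33 expected) at 1.5-fold. At 2-fold the 60-minute counts were 18 of 42 on the positive side (10.84 expected) and 0 of 3 on the negative side (0.77 expected). The positive side at 20 minutes held 4 of 20 at 2-fold (5.16 expected). Genes are not independent here, and no explanation was tested.

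Among 44 families of at least 5 named genes formed from the letters of their symbols, 0 passed in camera, at a preset or an estimated correlation. The unnamed probe with the highest mean, probe 532171, stood at 1.38, 3.42 and 4.33, above every named gene at 60 minutes. For the test of the mean ratio, turning the sign of 1 array gives 4 configurations, too few for a share under 0.05; the real one, 1 of the 4, gave 19 calls and the highest of the others 0.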
